A study of Mus musculus with 9 samples.

How the data were processed

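The series holds 9 Affymetrix arrays of mouse spermatogonia, 3 from mice on a normal diet, 3 from mice on a vitamin A-deficient diet for 18 weeks and 3 for 25 weeks. Per the labels' protocols, germ cells from 2 mice per preparation were separated on an albumin gradient after overnight plating, and 100 ng of total RNA was amplified in the Affymetrix protocol of 2 cycles. The deposited values are MAS5 intensity per probe set on a linear scale, per the submitters' processing notes and the range of the values. The version and target of the MAS5 scaling are not given in the sources used here, and detection calls were not used here. The trimmed means of the deposited signals differ between arrays, so they do not share a common target.

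Signals were transformed as log2(signal + 3.259), where the pseudocount is the 25th percentile of all deposited signals, so fold changes of low signals are understated. The medians of the arrays on that scale spanned 1.56, above the limit of 0.5 set before the data were examined, and by that rule quantile normalization between arrays became the main setting and the deposited scaling the alternative. Quantile normalization sets every array to the same distribution, and changes are therefore relative to it. The scaling mattered, since the median log2 change of all kept probe sets at 18 weeks without a block was 0.05 after quantile normalization, 0.24 after median centring and 0.66 on the deposited scale, and at 25 weeks it was -0.01, 0.08 and 0.93. The 64 control probe sets were left out, and probe sets with a mean at or above the 40th percentile were kept, 27022 of 45101. A platform table gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9211, and only those with 1 were named. Of these symbols, 34754 were found in a reference gene table of assembly GRCm38.p6 through their gene identifier. No coordinates are given because the files name no genome build. Each gene was represented by its brightest kept probe set, with probe sets prone to cross-hybridisation used last, and no probe set was compared in level with another.

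Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a trend in the variance) over all 9 arrays, so that the groups share 1 estimate of the spread, with a Benjamini-Hochberg adjusted p under 0.05 per comparison and no fold limit. The model fixed before the data were examined had group as its sole term and 6 residual degrees of freedom. After it called 0 probe sets, the arrays were examined for sets that differ by something other than group. Arrays whose trimmed mean (2% from each end) was under 0.5 of the median formed the dim pair, and arrays whose poly-A controls exceeded 10 times the median formed a second set. A block for the dim pair (5 residual degrees of freedom), a block of 3 sets (4), leaving out the pair, and scaling before the pseudocount were then run, and all were chosen after seeing the data. The block of 3 sets fits the arrays of the dim pair exactly, so its 25-week comparison rests on that pair with no estimate of the pair's noise.

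On simulated data with the real means, spread and dim-pair offsets over 27022 probe sets, 200 of them changed, the model fixed beforehand recovered 0 of 100 changes of log2 size 1 and 14 of 100 of size 2 at 18 weeks, and 0 and 13 at 25 weeks. The block model recovered 26 and 69 of 100 at 18 weeks with 5 false calls, and 33 and 78 at 25 weeks with 2 false calls. The noise in these simulations, with the spread of each array, was taken from the block model, so they show what each model recovers if that description of the arrays holds.

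Gene lists, 28 in all, were fixed before the data were examined, and 27 had at least 4 measured members. Red blood cell genes had 1 measured member and were not tested. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists of a comparison, and no list call held with an estimated correlation. Members past the threshold were counted over all probe sets and adjusted over the list alone. Genes named in the text were chosen by a rule fixed beforehand, applied to the block model as well as to the first model. For each comparison it takes the 10 highest and the 10 lowest log2 fold changes among named genes past the threshold whose replicates do not overlap between the groups, or, with fewer than 5, those with the smallest p up to 5. It adds up to 4 members of each list with the smallest p, and 12 fixed genes. The text also names 5 list members outside this rule, Dhh, Wt1, Dusp1, Jun and Psmc3ip, which were chosen after their values were seen. Regroupings of the 9 arrays were first counted as labelled assignments, in which relabelled copies of the real grouping entered as others. After that result was seen the count was corrected so that each grouping enters once, with 100 drawn, because a relabelled copy of the real groups is no other grouping.

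Replicate numbers are shared by the groups and were not used as pairs in the main model. RNA quality ratios were compared with an exact permutation test, two-sided. The alternatives set beforehand were the deposited scaling, median centring, pseudocounts of 1 and 11.46, no filter and a filter at the 60th percentile, no variance trend, array weights, only the groups compared, the replicate block, leaving out each array, a fold of at least 2, and limma's treat at a fold of 1.5. Figures were drawn with matplotlib.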

Results

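Gene expression was measured in spermatogonia of adult Balb/C mice that had eaten either a control diet or a diet without vitamin A (VAD, vitamin A deficiency). Vitamin A is the source of retinoic acid, which drives undifferentiated spermatogonia into differentiation. The cells came from testes of 2 mice per preparation, were separated by sedimentation velocity, and had a stated purity above 90%. The 9 arrays formed 3 groups of 3, namely control, VAD at 18 weeks and VAD at 25 weeks. Whether each array held a separate preparation is not stated, and neither is the age of the control mice, so the p-values below measure only the spread between these samples, and the number of arrays limits the precision of every value. Of 45101 probe sets, 27022 passed the filter on signal, and they covered 13616 named genes.

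The arrays did not form a uniform set. Control replicate 3 and VAD 25-week replicate 3, called the dim pair here, had trimmed mean signals of at most 23.3, against 55.6 to 186 on the other 7 arrays. After normalization the dim pair correlated with each other at r = 0.889 across probe sets and with the other arrays at 0.776 to 0.809, while the other 7 correlated at 0.936 to 0.981. The remaining 25-week arrays, replicates 1 and 2, were the brightest and carried strong signal from bacterial poly-A control transcripts. The model fixed before the data were examined, with group as its sole term, called 0 probe sets in all 3 comparisons. A model with an added block for the dim pair was chosen after that result was seen, and its values are given below as such. It was 1 of 4 changes tried at that stage, the others being a block of 3 array sets, leaving out the dim pair, and scaling the arrays before the pseudocount.

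**Figure D1:**
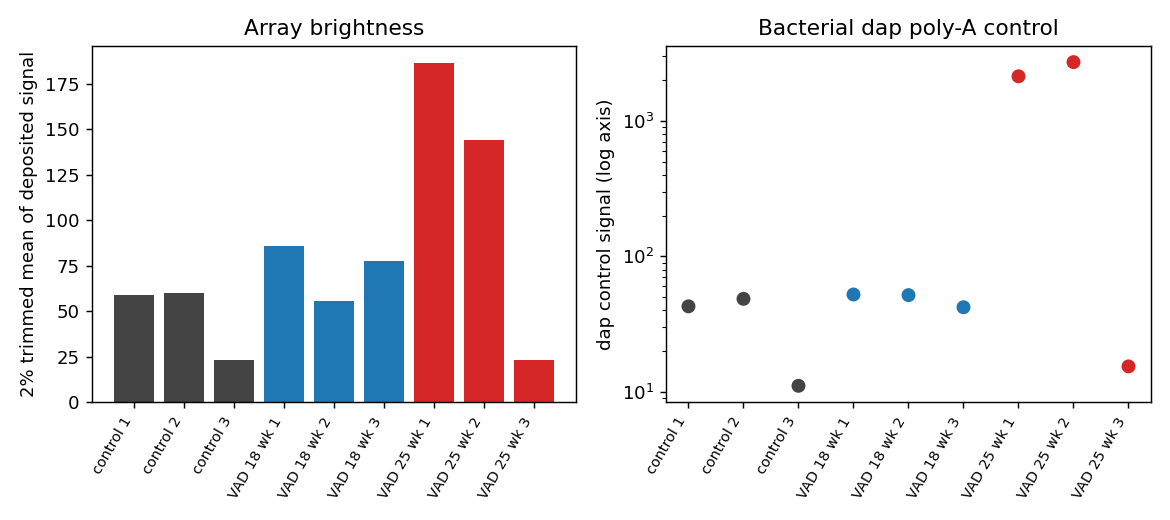
Left, bars give the 2% trimmed mean of the deposited signal on each of the 9 arrays; right, points give the signal of the bacterial dap control on a log axis. Control replicate 3 and VAD 25-week replicate 3 are far dimmer than the others, at no more than 23.3, and the dap signal is 2137 and 2720 on VAD 25-week replicates 1 and 2 against 11.1 to 52.3 elsewhere.

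The comparison of VAD at 18 weeks with control asks which transcripts differ in the spermatogonia preparations after the shorter time on the diet. The share of other cells in these preparations was not measured here. With the dim pair as a block, Gja1, which encodes the gap junction protein connexin 43, was higher by 3.53 ± 0.43 on the log2 scale (SE, n = 3 per group). The block's offset is estimated from the control arrays and the VAD arrays of the longer diet together. Those VAD arrays therefore enter the 18-week values of the block model, which are not plain differences of group means. The largest increases also included markers of Sertoli cells, the somatic nurse cells of the seminiferous tubule, with Cst12 higher by 3.04 ± 0.48, Cldn11, a tight junction protein of the blood-testis barrier, by 2.80 ± 0.45, and Ctsl, a lysosomal protease, by 2.77 ± 0.41. Limma's adjusted p for these 4 genes lay between 0.0052 and 0.0151 with the block and was 0.244 for each without it. Tmem255a (3.66), Gpm6b (2.96), Reep1 (2.89), Amhr2 (2.75), Lpar3 (2.69) and Mmd2 (2.59) completed the 10 largest increases. The largest decreases were in Ror2 (-2.31 ± 0.42), a receptor for Wnt ligands, and Slc1a5 (-1.88 ± 0.39), a glutamine transporter, followed by Plk5 (-1.64), Prr22 (-1.27), Krt8 (-1.25), Tcl1b3 (-1.20), Mtmr14 (-0.85), Agtr1a (-0.81), Ptchd3 (-0.80) and Map4 (-0.69).

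Of 23 measured Sertoli cell markers, 6 rose at 18 weeks and 0 fell (14 rose when adjusted over the list alone), with a median of 1.32 on the log2 scale. Limma's camera test placed the list above other genes with an adjusted p = 1.82e-09, which became an adjusted p = 0.416 with an estimated correlation. In the model without the block the median was 0.94, with a camera adjusted p = 2.19e-09 in limma and an adjusted p = 0.541 with an estimated correlation. Dhh (1.95 ± 0.39), a signal from Sertoli cells to Leydig cells, and Aard (2.25 ± 0.40) were among those that passed. The 11 Leydig cell markers had a median of 0.87 with 0 members past the threshold (2 when adjusted over the list alone), limma camera adjusted p = 0.00501 and an adjusted p = 0.629 with an estimated correlation. Without the block the Leydig median was 1.48 (limma camera adjusted p = 0.00122, adjusted p = 0.597 with an estimated correlation). Of the Sertoli markers 1 is also in the list of growth factor signals, and of the Leydig markers 4 are also in the list of cholesterol and steroid synthesis. Markers of peritubular myoid cells (median -0.22), leukocytes (-0.15), endothelial cells (0.01) and fibroblasts (-0.15) were not called at 18 weeks.

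Among genes of the germ cell lists at 18 weeks, Id4, a transcriptional regulator of undifferentiated spermatogonia, rose by 0.92 ± 0.14 (limma adjusted p = 0.0125 with the block, 0.273 without). Here too the cells behind the changes were not identified. Tex101, a germ cell surface protein, rose by 1.42 ± 0.15, and Sycp3, a component of the synaptonemal complex, by 0.80 ± 0.12. Of 18 piRNA pathway genes, which silence transposons, 3 rose, namely Piwil2 (1.06 ± 0.12), Piwil1 (0.97 ± 0.14) and Tdrd9 (0.67 ± 0.14), and 0 fell (6 rose when adjusted over the list alone). That list had a median of 0.15, limma camera adjusted p = 0.0118 and an adjusted p = 0.422 with an estimated correlation. Without the block its median was 0.33 (limma camera adjusted p = 0.00254, adjusted p = 0.541 with an estimated correlation). The 40 spermatid genes lay below other genes with a median of -0.39 (limma camera adjusted p = 3.75e-09, adjusted p = 0.423 with an estimated correlation), although 0 of them passed singly, also when adjusted over the list alone. The 28 pachytene spermatocyte genes had a median of -0.25, with 2 higher and 1 lower, limma camera adjusted p = 0.0118 and an adjusted p = 0.416 with an estimated correlation (2 higher and 2 lower when adjusted over the list alone). The higher members were Piwil1 and Tesmin (0.62 ± 0.14), and the lower one was Zpbp (-0.49 ± 0.11). In the model fixed beforehand the spermatid median was -0.14, or 0.56 on the deposited scale and 0.14 after median centring (limma camera adjusted p = 0.00122, adjusted p = 0.629 with an estimated correlation), and the pachytene list, at -0.10, was not called (limma camera adjusted p = 0.331). That model placed the 33 meiotic prophase genes above other genes, with a median of 0.36 (limma camera adjusted p = 0.0328, adjusted p = 0.629 with an estimated correlation), and with the block their median was 0.05 and the list was not called (limma camera adjusted p = 0.256; 1 gene, Sycp3, rose, and 4 when adjusted over the list alone).

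The genes fixed in advance for their place in retinoid signalling and spermatogonial identity mostly did not pass at 18 weeks. Kit, the receptor that marks differentiating spermatogonia, was at 1.08 ± 0.34 (limma adjusted p = 0.149), and Stra8, a target of retinoic acid, was at -0.86 ± 0.57 (limma adjusted p = 0.484). Values for Zbtb16 (-0.01), Gfra1 (-0.58), Rarg (-0.20), Lrat (-0.26), Cyp26a1 (0.75), Aldh1a1 (1.20) and Aldh1a2 (0.19) did not pass, and Rara was below the signal filter. Of 14 retinoic acid induced genes, 1 rose, Rarres1 (2.03 ± 0.38), and 0 fell (2 and 1 when adjusted over the list alone). Of 24 genes of retinoid uptake, storage and metabolism, 0 passed, also when adjusted over the list alone. The filter kept 18 of the 35 undifferentiated spermatogonia genes on the array and 17 of 18 for differentiating spermatogonia, against 28 of 28 for pachytene spermatocytes and 40 of 40 for spermatids. Of 18 genes of undifferentiated spermatogonia Id4 alone rose, and of 17 genes of differentiating spermatogonia Tex101 alone did (1 higher for the first list, and 2 higher and 2 lower for the second, when adjusted over the list alone).

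**Figure D2:**
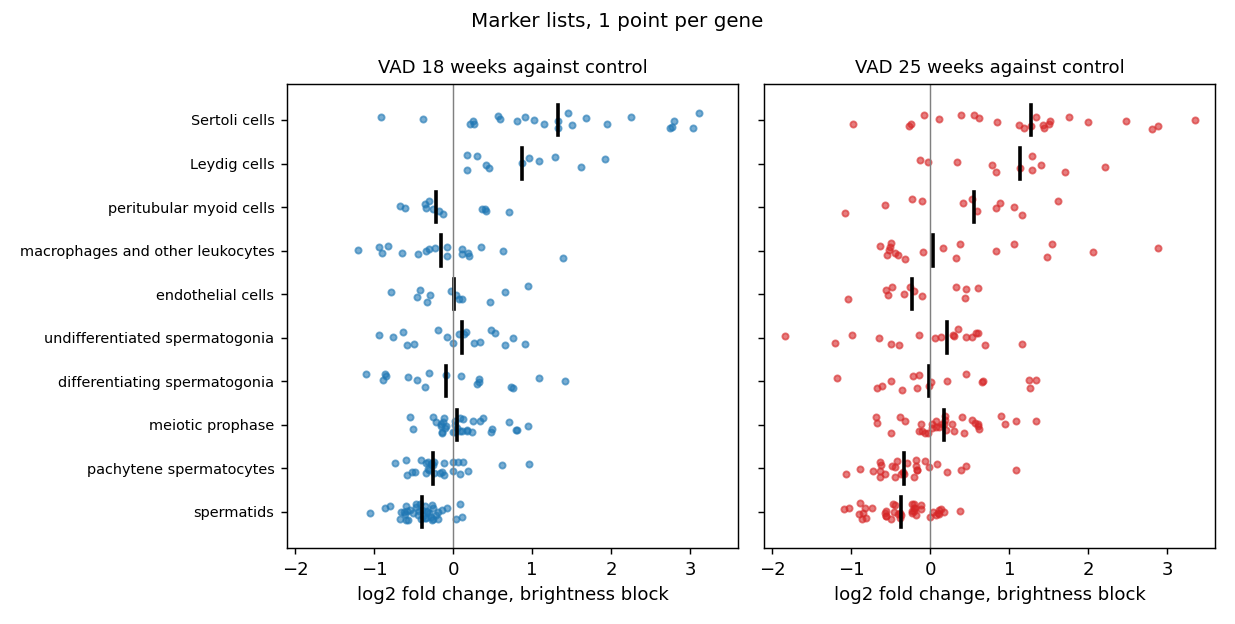
Each point is 1 gene's log2 fold change against control (horizontal axis) from the model with the dim pair as a block, in rows by marker list, at 18 weeks (left) and 25 weeks (right); black bars are list medians. Sertoli cell markers have medians of 1.32 and 1.27, and spermatid genes have medians of -0.39 and -0.37.

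In total, limma called 0 probe sets at 18 weeks in the model fixed beforehand (1955 at an unadjusted p under 0.05, smallest adjusted p 0.244) and 394 with the block (358 higher, 36 lower). Array weights, an alternative set before the data were examined, gave 723 calls without a block. With median centring in place of quantile normalization the block model called 317 higher and 165 lower, on the deposited scale 132 higher and 2 lower, and with no trend in the variance it called 0. It called 19 with the replicate numbers as a further block, 238 with a fold of at least 2, 2 with limma's treat at a fold of 1.5, and 1086 with array weights. The 18-week count with the block was 37, 38 and 1033 without control replicate 1, 2 and 3, 183, 68 and 85 without VAD 18-week replicate 1, 2 and 3, and 143, 138 and 988 without VAD 25-week replicate 1, 2 and 3. Without the dim pair it was 1074, and 393 of the 394 block calls were among these.

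The comparison of VAD at 25 weeks with control asks the same of a longer deficiency. No control array carries the poly-A signal of VAD 25-week replicates 1 and 2, and the block covers only the dim pair. Outside that pair, the different handling of those arrays cannot be told apart from the deficiency. The dim pair holds 1 control and 1 VAD 25-week array, so the block leaves the 25-week log2 fold changes as they are and alters only their errors. The immediate early gene Fos was higher by 3.97 ± 0.55 (SE, n = 3 per group), Gja1 by 3.61 ± 0.40, the inducible heat shock protein gene Hspa1b by 3.37 ± 0.56, and Clu, an abundant Sertoli cell transcript, by 3.35 ± 0.68. Limma's adjusted p for these 4 genes lay between 0.000562 and 0.00885 with the block and between 0.0854 and 0.173 without it. Bhmt (3.25), Eid1 (2.98), Lyz1 (2.88), Cldn11 (2.88), Mapre2 (2.81) and Ctsl (2.80) were the other members of the 10 largest increases. The largest decreases were in Muc1 (-2.43 ± 0.50), Emid1 (-2.38 ± 0.39) and Hkdc1 (-2.17 ± 0.40), followed by Gtsf1l (-2.04), Oas1a (-1.90), Nono (-1.89), Rsad2 (-1.88), Itgb1 (-1.84), Togaram2 (-1.78) and Wnt7b (-1.77). Without the dim pair Rsad2, Itgb1 and Wnt7b did not pass (limma adjusted p = 0.0594, 0.0839 and 0.136).

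Of the 23 Sertoli cell markers, 12 rose at 25 weeks and 0 fell (14 and 1 when adjusted over the list alone), with a median of 1.27. The list's limma camera adjusted p was 4.28e-05 with the block and 1.71e-07 without it, with an adjusted p = 0.588 and an adjusted p = 0.536 with an estimated correlation. Cst12 (2.48 ± 0.45), Aard (1.99 ± 0.38) and Wt1 (1.27, limma adjusted p = 0.106 without the dim pair) were among them. Within the dim pair alone, the median difference of the list between the 25-week and the control array was 1.94. Of 11 Leydig cell markers, Cyp17a1 (2.21 ± 0.51), an enzyme of androgen synthesis, and Fads1 (1.40 ± 0.37) rose (4 when adjusted over the list alone; limma adjusted p = 0.0628 and 0.0901 without the dim pair), with a list median of 1.14, limma camera adjusted p = 0.0361 and an adjusted p = 0.61 with an estimated correlation. Of 18 leukocyte markers, 5 rose and 0 fell (6 and 0 when adjusted over the list alone), among them Lyz1, C1qb (2.06 ± 0.41), Mrc1 (1.48 ± 0.31) and Csf1r (1.06 ± 0.29), while the list as a whole was not called (limma camera adjusted p = 0.455).

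Genes of the germ cell lists moved both ways at 25 weeks. Sertoli and Leydig markers had medians of 1.27 and 1.14 in the same comparison, and the cells behind the changes below were not identified. Id4 rose by 1.16 ± 0.13 (limma adjusted p = 0.000626), Kit by 1.34 ± 0.33 (limma adjusted p = 0.0188), and Tex101 by 1.25 ± 0.14, whereas Dmrtb1, a transcription factor that coordinates entry into meiosis, fell by 1.18 ± 0.11. Of 18 genes of undifferentiated spermatogonia 1 rose and 1 fell, and of 17 genes of differentiating spermatogonia 3 rose and 1 fell (the same counts when adjusted over the list alone), with limma camera adjusted p = 0.703 for both. Of 33 meiotic prophase genes, 7 rose, among them Tex12 (1.34 ± 0.21), Sycp2 (1.09 ± 0.19) and Sycp3 (0.94 ± 0.12), and 1 fell, Syce1 (-0.68 ± 0.11; 8 and 1 when adjusted over the list alone), and the list was not called (limma camera adjusted p = 0.0828). Of 28 pachytene spermatocyte genes, 12 fell, including Ccna1 (-0.89), and 3 rose, with a median of -0.33, or 0.47 on the deposited scale (13 and 3 when adjusted over the list alone). Limma's camera gave that list an adjusted p = 0.00224, and an adjusted p = 0.588 with an estimated correlation. Of 40 spermatid genes, 10 fell and 0 rose, with a median of -0.37, or 0.56 on the deposited scale (13 fell when adjusted over the list alone), limma camera adjusted p = 7.75e-05 and an adjusted p = 0.598 with an estimated correlation. Crem, a transcription factor of spermatids, was at -1.09 and Acr, the acrosomal protease acrosin, at -0.83. These decreases are relative to the normalized arrays, since with the deposited scaling Ccna1 (0.08), Syce1 (0.17) and Acr (0.14) lay above control without passing. Of 18 piRNA pathway genes, 7 rose and 2 fell (7 and 3 when adjusted over the list alone), including Piwil1 (1.08 ± 0.13) and Piwil2 (0.80 ± 0.11), and the list was not called (limma camera adjusted p = 0.103).

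**Figure D3:**
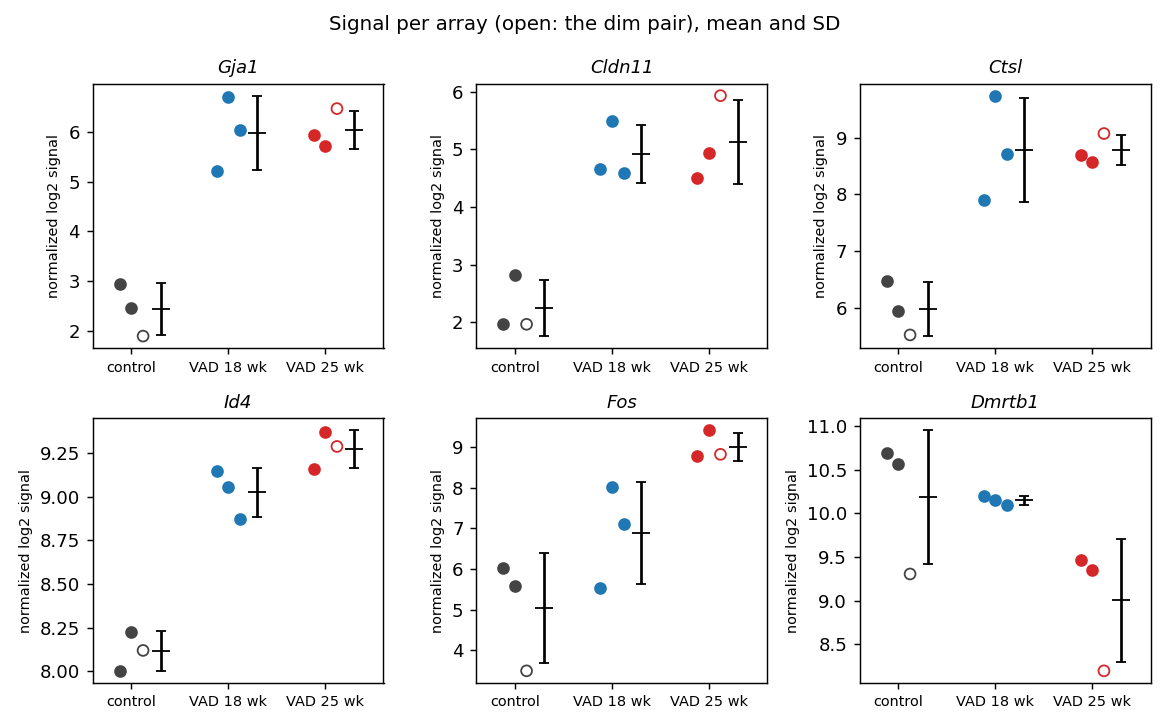
Each panel plots the normalized log2 signal (vertical axis) of 1 gene on the 9 arrays by group, with open circles for the dim pair and the mean and SD of each group (n = 3) beside the points. Gja1, Cldn11, Ctsl and Id4 have all 6 VAD arrays above all 3 control arrays. For Gja1, Cldn11 and Ctsl the rule for naming the largest changes required this. Dmrtb1 shows control replicate 3 (9.31) below control replicates 1 and 2 (10.69 and 10.56).

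Retinoid genes at 25 weeks were mixed. Of 24 genes of retinoid uptake, storage and metabolism, 7 rose and 1 fell (8 and 3 when adjusted over the list alone). Aldh1a1, which makes retinoic acid from retinal, was at 2.23 ± 0.50 (limma adjusted p = 0.0128, and 0.0596 without the dim pair), and Fabp5, a carrier of retinoic acid, was at 2.07 ± 0.43, while Dhrs4 fell by 1.05 ± 0.21. Sertoli and Leydig markers had medians of 1.27 and 1.14 in this comparison. Which cells the retinoid changes came from was not tested. Of 14 retinoic acid induced genes, Rarres1 (2.14 ± 0.36) and Kit rose (2 higher and 1 lower when adjusted over the list alone). Of 16 receptors and cofactors, Ncoa2 (1.23 ± 0.17) and Nr2c2 (0.53 ± 0.12) rose and Ncoa3 (-0.80 ± 0.24) fell (2 and 1 also when adjusted over the list alone). Another probe set of Nr2c2 was called in the opposite direction, and with the deposited scaling Ncoa3 was at 0.28 (limma adjusted p = 0.108 without the dim pair). None of the 3 retinoid lists was called, with limma camera adjusted p = 0.262, 0.569 and 0.703. Stra8 (-0.15), Zbtb16 (0.45), Gfra1 (-0.65), Rarg (-0.45), Lrat (-0.03), Cyp26a1 (0.34) and Aldh1a2 (0.03) did not pass.

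Of 27 heat shock and stress genes, 5 rose at 25 weeks, Fos, Hspa1b, Fosb (2.06 ± 0.38), Dusp1 (1.91) and Jun (0.85), and 1 fell, Ddit3 (-0.98 ± 0.20; 7 and 1 when adjusted over the list alone). With the deposited scaling Ddit3 was at 0.09, and without the dim pair Jun had a limma adjusted p = 0.168. Fos, Fosb, Jun and Dusp1 are genes of the immediate early response to stimulation or cell handling, not chaperones. The list had a median of 0.39, limma camera adjusted p = 0.0361 and an adjusted p = 0.588 with an estimated correlation.

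In total, limma called 0 probe sets at 25 weeks in the model fixed beforehand (3211 at an unadjusted p under 0.05, smallest adjusted p 0.0854) and 3999 with the block (2300 higher, 1699 lower). Array weights without a block gave 5638 calls, and leaving out VAD 25-week replicate 3 from the model fixed beforehand gave 28. The direction of the calls moved with the scaling, with 2790 higher and 822 lower after median centring and 10571 higher and 7 lower on the deposited scale, where the median of all probe sets lay at 0.93. The block model called 2378 with no trend in the variance, 2591 with the replicate numbers as a further block, 1737 with a fold of at least 2, 142 with limma's treat at a fold of 1.5, and 7874 with array weights. The block count was 2091 and 2636 without control replicate 1 and 2, 1973 and 1785 without VAD 25-week replicate 1 and 2, and 4248 without the dim pair, of which 2878 were shared with the block calls. Of those 4248 probe sets, 79.1% had the same sign within the dim pair, against 61.1% of all probe sets.

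**Figure D4:**
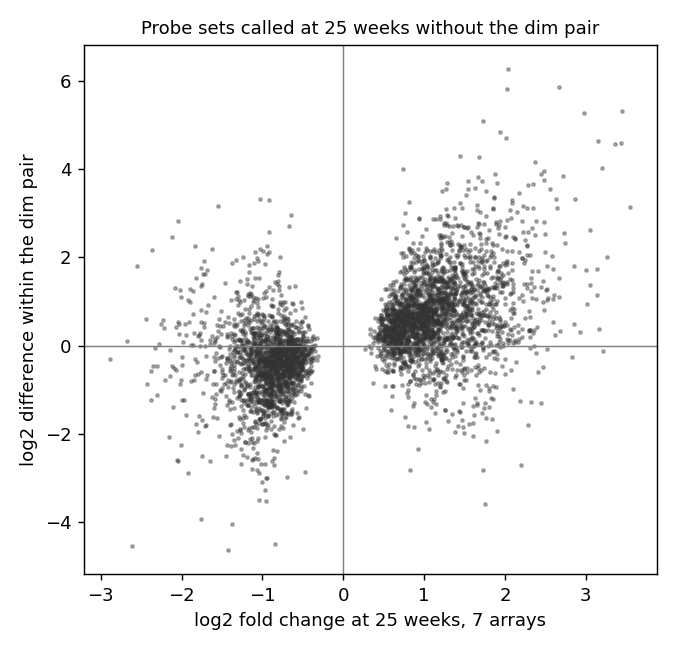
Each point is 1 of the 4248 probe sets called at 25 weeks without the dim pair, with its log2 fold change over the other 7 arrays (horizontal axis) against the log2 difference between the 25-week and the control array of the dim pair (vertical axis). Of them, 82.5% of the higher and 74.6% of the lower probe sets keep their sign.

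Between VAD at 25 and at 18 weeks, which tests whether the longer deficiency differs from the shorter, limma called 0 probe sets without the block (1031 at an unadjusted p under 0.05) and 0 with it (3124 at an unadjusted p under 0.05). By the smallest p with the block, Rpl27a (1.29 ± 0.18), Arglu1 (0.99 ± 0.15), Etnk1 (0.76 ± 0.13), Cald1 (1.92 ± 0.35) and Lyz1 (2.68 ± 0.51) were on the higher side and Clasrp (-1.22 ± 0.17), Dmrtb1 (-0.73 ± 0.11), Depp1 (-1.54 ± 0.24), Ttc25 (-0.92 ± 0.15) and Aplp2 (-0.79 ± 0.13) on the lower side, and none of these 10 passed (limma adjusted p = 0.133 to 0.138). Depp1 (0.48) and Aplp2 (0.34) were on the higher side without the block. The block's offset also rests on the control arrays, so those arrays enter the values with the block here. Leukocyte markers lay above other genes at 25 weeks, with a median of 0.59 without the block (limma camera adjusted p = 0.00148, adjusted p = 0.128 with an estimated correlation) and 0 of 18 past the threshold (4 when adjusted over the list alone). Mitochondrial respiration genes had a median of -0.27 in that model, with 0 of 86 past the threshold, also when adjusted over the list alone (limma camera adjusted p = 0.0063, adjusted p = 0.503 with an estimated correlation). With the block their median was -0.08 and the list was not called (limma camera adjusted p = 0.121). Array weights gave 920 calls in this comparison and leaving out the dim pair gave 445, and because the 18-week arrays all lay in 1 of the array sets, those sets and the diets are largely joined here.

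Across both deficient groups, the block model called 367 probe sets in the same direction at 18 and 25 weeks, 337 higher and 30 lower, and 0 in opposite directions. That count was 0 with no trend in the variance, an alternative set beforehand, 19 with the replicate numbers as a further block, 129 on the deposited scale (129 higher, 0 lower), and 297 higher and 82 lower after median centring. Lists of these sizes drawn independently would share 30.5 higher and 2.26 lower probe sets. Part of the excess may come from the controls that both comparisons share, since 3 controls are too few to be split. The covariance of the 18-week and 25-week log2 fold changes across probe sets was 0.226, against 0.0753 in 20 simulated data sets with unchanged groups and the same controls. Those simulations gave 0 calls in either comparison and so give no value for shared calls. Limma's F test for any difference among the 3 groups called 2543 probe sets with the block, and it called 0 without it, where the smallest adjusted p was 0.212. With the block it called 553 with no trend in the variance, 987 with the replicate numbers as a further block and 8472 on the deposited scale. The F count was 880 and 1052 without control replicate 1 and 2, 1631 without VAD 18-week replicate 2, and 936 and 828 without VAD 25-week replicate 1 and 2. The shared count was 36, 37 and 874 without control replicate 1, 2 and 3, 177, 66 and 84 without VAD 18-week replicate 1, 2 and 3, and 133, 133 and 829 without VAD 25-week replicate 1, 2 and 3. The model fixed beforehand called 0 in both groups.

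RNA quality was read from the ratio of 3' to 5' probe sets of beta-actin and Gapdh, which rises as RNA is degraded or shortened in amplification. The log2 ratio of beta-actin was 2.16 ± 0.38 in control, 2.42 ± 0.14 in VAD at 18 weeks and 2.75 ± 0.39 at 25 weeks (SD, n = 3), and that of Gapdh was 1.84 ± 0.25, 1.88 ± 0.23 and 2.14 ± 0.31. On the deposited signals the differences had two-sided exact permutation p between 0.2 and 1, where 3 arrays against 3 cannot give less than 0.1. After quantile normalization the actin difference was 0.74 at 25 weeks against control and 0.41 against 18 weeks, each with an exact permutation p of 0.1. These tests do not take the dim pair into account, within which the actin ratio was 3.32 in the control and 4.95 in the 25-week array. The Gapdh ratios of the dim pair, 4.36 and 5.61, were the highest of the 9 arrays. VAD 25-week replicates 1 and 2 had the highest actin ratios, 7.82 and 7.92, against 3.32 to 5.74 on the other arrays.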

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

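All tests and comparisons in this part other than the 25-week to 18-week list tests of the model fixed beforehand were chosen after the arrays had been examined. Groups of 3 arrays are too small for a test of single outlying arrays, and none was run.

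The bacterial poly-A controls, which are outside the comparisons of the report, gave signal on VAD 25-week replicates 1 and 2 far above every control array. Their mean over the highest control array was 49.9 for dap, 22.4 for lys, 23.1 for phe and 16.7 for thr. These transcripts are added to RNA before labelling, so the arrays were handled differently at that step from the other 7.

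Several lists differed between 25 and 18 weeks by the test of that difference itself. Without a block, leukocyte markers had a median of 0.59 (limma camera adjusted p = 0.00148, and adjusted p = 0.128 with an estimated correlation), and mitochondrial respiration genes had a median of -0.27 (limma camera adjusted p = 0.0063, and adjusted p = 0.503 with an estimated correlation), a call that the block ended (median -0.08, limma camera adjusted p = 0.121). With the block for the dim pair, peritubular myoid markers had a median of 0.42, leukocyte markers 0.34, and fibroblast and matrix genes 0.27, each with a limma camera adjusted p = 0.031 and an adjusted p = 0.498 with an estimated correlation. Heat shock and stress genes had a median of 0.23 (limma camera adjusted p = 0.0391, and adjusted p = 0.518 with an estimated correlation). Of 23 other settings, the block-model call held in 14 for peritubular myoid markers, 13 for leukocyte markers, 11 for fibroblast and matrix genes and 9 for heat shock and stress genes. The 25-week arrays with poly-A signal hold no other group, and no 18-week array lies in the dim pair, so no value within an array set can be given for this comparison.

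The dim pair was weighed against 2 technical explanations. Gene signals on control replicate 3 were 29.6% of the median of the other arrays and hybridisation controls, which are added after labelling, were 52.8%; on VAD 25-week replicate 3 the values were 30.0% and 82.3%. The larger ratio of the gene share to the control share was 0.56, which is consistent with less labelled RNA on both arrays. An exchange of the labels of this pair would turn the signs of the 25-week changes, and 79.1% of the probe sets called without the pair kept their sign in it, which argues against it. What made these arrays dim stays open, and no biological explanation was tested because the pair holds 2 groups.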

How the results depend on the processing

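The alternatives with a block, without the dim pair, or scaled before the pseudocount were chosen after seeing the data, and so was every alternative run on the block model. Signal over background limits what arrays show here, and whether the dim pair compresses its low signals was not measured. The cause of each change below was not tested unless stated.

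In the model fixed beforehand, counts at 18 weeks, at 25 weeks, between 25 and 18 weeks, in the F test and in both groups were all 0. They became 723, 5638, 920, 4108 and 674 with array weights, 394, 3999, 0, 2543 and 367 with the brightness block, 963, 5011, 1708, 5203 and 493 with the block of 3 processing sets, and 1074, 4248, 445, 3255 and 897 without the dim pair. At 25 weeks alone the count was 6 with the deposited scaling, 1 when scaled before the pseudocount, and 0 to 28 when leaving out each array. All other settings but the replicate block gave 0.

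In the block model the same 5 counts were 394, 3999, 0, 2543 and 367. They were 134, 10578, 1806, 8472 and 129 with the deposited scaling, 1086, 7874, 1547, 6475 and 999 with array weights, and 0, 2378, 0, 553 and 0 with no trend in the variance. A fold of at least 2 gave 238, 1737, 0, 1284 and 213 because it removes smaller changes, and treat at a fold of 1.5 gave 2, 142, 0 and 2, with no F test. The block of 3 processing sets gave 963, 5011, 1708, 5203 and 493, leaving out the dim pair 1074, 4248, 445, 3255 and 897, and scaling before the pseudocount 890, 4308, 0, 3139 and 786. With only the 2 groups compared, 38 were called between 25 and 18 weeks. No brightness block gave 0 throughout. Leaving out each array gave 37 to 1033, 1785 to 4183, 0 to 395, 828 to 3192 and 36 to 874. Between 25 and 18 weeks the count of 0 became 382 without control replicate 3, 395 without VAD 25-week replicate 3, and 1 without control replicate 2 or VAD 18-week replicate 2. Median centring, both pseudocounts and both filters left every count within 1.5 times.

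With the replicate block, the model fixed beforehand called 1 probe set at 25 weeks and 0 elsewhere, and the block model called 19, 2591, 0, 987 and 19. The numbers gave no pairing beyond the dim pair: deviations of same-numbered arrays of control and 18 weeks correlated at -0.00469, 0.027 and 0.0749, those of 18 and 25 weeks at 0.000557, 0.0337 and 0.0301, and those of control and 25 weeks at 0.525, 0.519 and 0.69, the last being the dim pair. Among the brighter arrays, unlike numbers correlated as highly, with 0.54 for control replicate 1 and 25-week replicate 2 and 0.529 for control replicate 2 and 25-week replicate 1.

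Of the 145 gene results called in the block model, 128 passed in the same direction without the dim pair and 0 did in the model without the block, where Ccnb2 at 18 weeks was at 0.00758. In the same direction 74 of 145 passed with no trend in the variance, 90 of 145 with the replicate block, 109 of 145 with the block of 3 processing sets, 81 of 143 on the deposited scale, and from 90 of 144 (without control replicate 1) to 130 of 145 (without VAD 25-week replicate 3) when leaving out each array. On the deposited scale, where the median 25-week change of all probe sets was 0.93, the sign turned for Ncoa3 (0.28), Syce1 (0.17), Ccna1 (0.0757), Spata16 (0.30), Insl6 (0.32), Acr (0.14), Tssk1 (0.20), Dnajb3 (0.34), Srf (0.18), Postn (0.53), Aurka (0.14), Ddit3 (0.0903), Fdft1 (0.0587), Gtsf1 (0.27), Ehmt2 (0.14), Rpl13a (0.41), Ndufa12 (0.20) and Psmd9 (0.19). Of 16 list calls in the block model, 0 held with an estimated correlation, 2 with fry and 9 to 16 in each other setting. At 25 weeks against control, the heat shock list held in 12 of 23 settings and the Leydig list in 11. The camera direction turned for mitochondrial respiration, at 18 weeks with the deposited scaling (0.12) and median centring (-0.0588) in the block model, and between 25 and 18 weeks with the block of 3 processing sets (-0.00329). Medians changed sign while the camera direction against other genes stayed for spermatids at 25 weeks (-0.37 to 0.56) and pachytene spermatocytes at 25 weeks (-0.33 to 0.47) on the deposited scale, for spermatids at 18 weeks in the model fixed beforehand (-0.14 to 0.56 on that scale and 0.14 with median centring), and for peritubular myoid cells between 25 and 18 weeks with the block of 3 processing sets (0.42 to -0.04). Sertoli cell medians ranged from 0.94 to 1.66 at 18 weeks and from 0.99 to 2.00 at 25 weeks, with limma adjusted p from 1.17e-28 to 0.416 and from 5.7e-12 to 0.588. Quantile normalization turned the Gapdh ratio difference at 18 weeks from 0.04 to -0.08.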

Other observations

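The tests of explanations in this part were chosen after the results they bear on had been seen, and so was the rule by which regroupings of the 9 arrays are counted, while the tests over splits of 6 arrays were set before they were run. All gene values come from the model with the dim pair as a block, itself chosen after seeing the data.

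Genes of cell division went both ways at 25 weeks, where 1294 of all 13616 genes rose and 1070 fell. Of 31, Ccne2 (2.01 ± 0.25), which drives entry into S phase, and the replication inhibitor Gmnn (0.51 ± 0.13) were among 4 that rose, whereas the mitotic kinases Plk1 (-1.03 ± 0.19) and Aurka (-0.72 ± 0.11) were among 5 that fell (4 and 8 when adjusted over the list alone), and the list was not called (limma camera adjusted p = 0.156). At 18 weeks Ccne2 was at 1.32 ± 0.27 and Ccnb2 fell by 0.66 ± 0.14, the latter lying at 0.01 without the block. Of 27 genes of DNA and histone methylation, 7 rose at 25 weeks, among them the polycomb ubiquitin ligase Rnf2 (1.90 ± 0.19), the histone demethylase Kdm5a (1.15 ± 0.18) and the methyltransferase Kmt2d (1.23 ± 0.25), and 3 fell, including Ehmt2 (-0.77 ± 0.15; 8 and 3 when adjusted over the list alone; limma camera adjusted p = 0.132). Aurka and Ehmt2 were at 0.14 on the deposited scale.

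Protein turnover and respiration genes also went both ways at 25 weeks, where 1294 of all 13616 genes rose and 1070 fell. The respiration and cholesterol counts below lie near these shares, so they show no trait of those lists. Of 37 proteasome genes, 8 rose, including the germ cell subunit Psma8 (0.71 ± 0.09) and Psmc3ip (0.40), a factor of meiotic recombination that the list holds by its symbol, and 3 fell, including Psmd9 (-0.85 ± 0.15). Of 86 respiration genes, 8 rose, among them Atp5pb (0.99 ± 0.15) and Ndufa1 (0.95 ± 0.16), and 5 fell, among them Ndufa12 (-0.70 ± 0.11); on the deposited scale Psmd9 (0.19) and Ndufa12 (0.20) lay above control. At 18 weeks these lists had medians of 0.18 and 0.11 (limma camera adjusted p = 0.0106 and 0.0118, and adjusted p = 0.393 and 0.416 with an estimated correlation), and without the block 0.26 and 0.34 (limma camera adjusted p = 0.00854 and 0.00122, and adjusted p = 0.597 and 0.629 with an estimated correlation). In the block model the camera direction of the respiration list turned on the deposited scale (median 0.12) and with median centring (median -0.0588). Of 24 cholesterol and steroid genes, Hmgcs1 (0.93 ± 0.18) and Cyp17a1 rose and Fdft1 (-0.89 ± 0.11) and Mvk (-1.21 ± 0.27) fell, of which Fdft1 was at 0.06 on the deposited scale.

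Of 23 Sertoli cell markers, 6 rose at 18 weeks and 12 at 25 weeks, and 21 and 19 lay above 0, the list calls being lost with an estimated correlation (limma camera adjusted p = 0.416 and 0.588). A lower share of germ cells that raised every other cell type alike would lift the other lists as far as the Sertoli list. Instead, the Sertoli list exceeded the 73 measured markers of Leydig, peritubular, leukocyte, endothelial and fibroblast cells by 1.35 in median at 18 weeks and by 0.944 at 25 weeks (permutation p = 1e-05 and 0.00142 over genes, which are not independent). With the Leydig list left out the difference was 1.47 at 18 weeks. The Sertoli list did not stand apart from the 11 Leydig markers alone, with differences of 0.449 and 0.128 (permutation p = 0.266 and 0.762). Without the block the Leydig median at 18 weeks, 1.48, was above the Sertoli median of 0.94. Of the 73 markers, 62 belong to the 4 lists not called at 18 weeks, and fold changes of low signals are understated. The comparison bears only on an equal rise. A lower share of germ cells with unequal rises stays open, as does a rise shared by Sertoli and Leydig cells. The dim pair was not needed for the rise of the Sertoli list itself against control at 18 weeks. Its median without the pair was 1.24 (limma camera adjusted p = 1.46e-08, and adjusted p = 0.514 with an estimated correlation). The difference from the other lists was not computed without the pair. Within the dim pair, 82.6% of the markers were higher in the 25-week array, against 49.3% of all 13616 genes, but the pair is part of the comparison and sets 1 array against 1, so more Sertoli cells carried through the overnight plating and sedimentation and more of these transcripts per cell both stay open.

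With the block, 25 weeks gave more calls than 18 weeks, 3999 against 394. The direct test between 25 and 18 weeks called 0 in that model, and 445 without the dim pair. More arrays behind the 25-week comparison does not account for all of the excess. Without the dim pair, where 25 weeks rests on fewer arrays, its count was still 3.96 times that of 18 weeks, at 4248 against 1074. That ratio was smaller than with the block because the 18-week count rose from 394 to 1074, while the 25-week count rose from 3999 to 4248. Leaving out the pair changes more than the number of arrays, so whether that number accounts for a part cannot be told. The dim pair carries no poly-A signal and kept the sign of 79.1% of the 25-week calls made without it, against 61.1% of all probe sets. This cannot tell whether separate preparation of the arrays with poly-A signal made the excess over 18 weeks. Signs were not counted for the excess calls alone, and the pair sets 1 array against 1. Within the pair, the median size of the higher calls fell from 1.10 to 0.64. That of the lower calls went from -0.89 to -0.38. These calls were chosen on the other arrays, so smaller sizes in the pair can follow from that choice alone. They cannot show whether a part came from that preparation. That preparation, the longer deficiency, the age of the mice and RNA quality were not tested apart. Actin ratios were highest on VAD 25-week replicates 1 and 2 (7.82 and 7.92).

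Splits of the arrays were counted for each model. In the model fixed beforehand, all 10 splits of the 6 arrays of each comparison gave 0 calls, the real one included, and 10 splits are too few for a share under 0.05. All 100 groupings of the 9 arrays gave 0 in the F test and 0 shared calls. With the block, the real split gave 394 at 18 weeks and 3999 at 25 weeks against 0 in the highest other split (1 of 10 splits as large in each), and 0 between 25 and 18 weeks against 1 in another split (10 of 10 as large), where again 10 splits are too few. For the F test 1 of 100 groupings, the real one, gave as many as 2543 (highest other 579), and for the shared calls 2 of 100 gave as many as 367, both shares lying under 0.05 within a model that was itself chosen after seeing the data. The other grouping, with 583 shared calls, kept the 3 controls together and mixed the deficient arrays. The real grouping also places both arrays with poly-A signal in 1 group and all 18-week arrays in 1 array set. These shares therefore cannot tell the diet from the array sets.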
